A study of Mus musculus and Homo sapiens with 201 samples.

How the data were processed

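Promoter capture Hi-C contact lists of 8 HCT-116 libraries and sgRNA tables of 2 CRISPR screens were used, 10 of the 201 samples of the series. The other samples were not analysed here. The libraries belong to the groups untreated (replicates 1 and 2), auxin (1 and 2), amanitin (3 and 4) and both treatments (4 and 5). Treatments were read from the sample titles, and doses and times are not given in the sources used here. In the screens ES cells infected with lentiCas9, or CD4+ T cells from Cas9 mice on plates with antibodies to CD3 and CD28, received the sgRNA library at a multiplicity of infection of 0.3 with puromycin from 24 h, and libraries were made at day 0 and day 21, in 4 replicates for ES cells and 1 for T cells. The labels of both screen samples name the same ES cell table, and the T cell sample lists both CD4+ T cells and ES cells as its source, so the cell type of each table was taken from the name of the table. Auxin in cells without the degron was not analysed here.

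In the contact lists the read counts, as deposited by the authors, are whole numbers of reads per pair of bait fragment and other-end fragment, with no normalization, and pairs with under 2 reads or a score under 5 are not listed. The score of each contact is as deposited by the authors, and the tool that gave it is not given in the sources used here. The submitters' processing notes for these libraries name CASAVA 1.8.2, Bowtie2 2.3.4.3, cutadapt, Bismark and BS-Seeker2 and the builds hg19 and mm9. Those for the screens name CASAVA 1.8.2, Bowtie 1.1.1, SAMtools 1.2, bedtools 2.25 and BWA. No role is stated for any of them. In the screens the sgRNA counts are whole numbers as deposited by the authors, and the percent values are each count as a percentage of its library's total, computed by the authors. Positions are in hg19, the human build the notes list.

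All listed contacts lie within 1 chromosome. Bait fragments (31268) were joined by gene symbol into 16017 promoters, and fragments that carry several genes keep all symbols. The files annotate activity and CTCF binding only for bait fragments with a gene on the plus strand, 14468 of 17136 such fragments and 0 of 14132 with minus-strand genes only, so statements on active or CTCF-marked promoters cover the former. Of those annotated, 9471 are marked active and 2742 as bound by CTCF. Other-end fragments have a median length of 547 bp.

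Reads of listed contacts within 2 Mb were summed per promoter, and again for contacts from 100 kb to 2 Mb, and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood F test, 1 mean per group over all 8 libraries, Benjamini-Hochberg threshold 0.05) under R 4.3.3. The contact test used pairs of fragments listed in all 8 libraries, 213 in number. There filterByExpr was applied as well, which left 140 pairs. The written design named only the listing in all libraries for such files, while the list of alternatives named the filter as the choice and no filter as the alternative. Both versions gave 0 pairs in every contrast. A sum over listed contacts moves with how much was listed, so the number of contacts and the mean reads per contact are given per group of libraries. They are not given per promoter. The sum of a promoter therefore cannot tell fewer reads from contacts that dropped under the listing threshold. No fold is given where no read was listed in a group, and reads are given in place of a fold where a group held at most 3. The standard error of a log2 change is its size divided by the square root of the F statistic, from a fit that pools the spread over all libraries.

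Median distances and shares of contacts were compared between the 4 libraries with a treatment and the 4 without by two-sided exact permutation tests, with Benjamini-Hochberg adjustment over 40 comparisons. Shared contacts have the same fragments at both ends. Gene lists were tested with limma 3.58.1, using camera with a preset correlation of 0.01 and again with an estimated one, and fry, over 18 lists and 6 contrasts, 108 tests in each family. The lists were colon epithelium, Wnt targets, p53 targets, immediate early genes, housekeeping genes, cohesin and CTCF, Mediator subunits, Pol II subunits, developmental transcription factors under Polycomb, neuronal, blood cell, hepatocyte, and muscle and fibroblast markers, HOX genes, clustered protocadherins, replication histones, olfactory receptors and zinc finger genes of chromosome 19.

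Promoters named are, per contrast, the 8 largest rises and 8 largest falls among those past the threshold whose replicates of the compared groups did not overlap, up to 4 members of each list past the threshold, and MYC, AXIN2, CDX1, CDX2, KLF5, SOX9, CDKN1A, EGR1, RAD21 and POLR2A whatever their result. Where many qualified, a part is given. In the screens every Mediator gene is named.

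For ES cells edgeR tested the 152 sgRNAs (33 genes and 4 control sgRNAs) between days, scaled to total counts, and the median over its sgRNAs gives a gene's value. The values printed with an SD are means over the 4 replicates of each replicate's own gene median, and differences from T cells use the medians of the fit. T cell changes used a pseudocount of 0.5. The design had named a permutation test of each gene's sgRNAs for a screen with 1 library per day; in its place the percentile of the gene median among 10000 random sets of as many sgRNAs is given, as a description without a p. Screens were compared by exact sign-flip tests over a gene's sgRNAs. Lists of pluripotency, T cell and core essential genes had no member among the sgRNAs.

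Groups, tests, lists, the rule for naming and most alternatives were fixed before the data were examined. Chosen after seeing the data were the contrast of both treatments against auxin, the medians by promoter and fragment class and the share of contacts whose other end carries a gene name, the camera tests of CTCF-marked and active promoters, the comparison with mirrored positions, the fits with 1 treatment term over other splits of the libraries, and these alternatives: the same number of top-scoring contacts for the distance profile, fits of the 4 untreated and auxin libraries alone without a block, an additive model of both treatments, and for the screen a replicate block and leaving out each replicate. The alternatives fixed beforehand were DESeq2 1.42.0 size factors and its Wald test, no filter, a replicate block, leaving out each library, a score of at least 10, all cis contacts, contacts over 20 kb, a bound of 200 kb, library factors from contacts under 100 kb, offsets by distance, shares of reads, other ends within 5 kb, estimated correlation, means over sgRNAs, a minimum of 30 counts, and scaling to control sgRNAs or the median sgRNA.

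On simulated data with 100 promoters changed in the same libraries, the long-range test for auxin recovered 1% of 2-fold and 36% of 4-fold changes, and the test of all contacts 0% and 25%. Camera with the preset correlation was run per test on a single list of 40 promoters lowered 2-fold, simulated without correlation between promoters. It gave an unadjusted p under 0.05 both times, which is not a recovery rate. For the amanitin contrast recovery of promoters was 0% and 29% in long-range reads, and the screen test recovered 40% and 95% of changed sgRNAs. The screen test also called 5 unchanged sgRNAs, and the promoter tests called 0 to 4 unchanged promoters. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for the rest.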

Results

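The series addressed whether Mediator, the complex that relays signals from enhancer-bound factors to RNA polymerase II (Pol II), acts as a structural link between promoters and enhancers. Of its 201 samples, the processed data of 10 were analysed here. Of these, 8 were promoter capture Hi-C libraries of HCT-116, a human colon carcinoma line, in which ligated DNA pairs are enriched for annotated promoters so that the fragments each promoter touches can be listed. In this line the cohesin subunit RAD21 carries a degron, a tag through which auxin triggers degradation of the protein, and the Pol II genotype is given as +/-. The libraries fell into 4 groups of 2, namely untreated cells, cells given auxin, cells given alpha-amanitin (an inhibitor of Pol II) and cells given both. The other 2 samples were CRISPR screens of Mediator genes, in mouse E14 embryonic stem (ES) cells and in primary mouse CD4+ T cells.

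The libraries listed between 152176 and 248639 contacts each, supported by between 461238 and 842103 reads, and every contact joined fragments of the same chromosome. The mean number of listed contacts was 221907 ± 37805 (SD, n = 2) in untreated cells, 166053 ± 19625 with auxin, 193806 ± 14262 with amanitin and 172479 ± 25752 with both. The mean reads per contact lay between 3.08 and 3.22 in the 4 groups. A contact was listed only with at least 2 reads and a score of at least 5, so a missing contact is not a count of 0, and the full sequencing depth behind the lists is unknown. Of 1339614 distinct pairs of fragments, 91.2% were listed in 1 library only and 213 in all 8. The ES cell screen held 8 libraries of 863366 to 3322807 sgRNA counts, and the T cell screen held 1389395 counts at day 0 and 1190246 at day 21. The titles number the contact libraries with br, where other samples of the series carry br and tr numbers, and do not spell out either. No label says that replicates came from separate cultures or animals, so p-values measure the spread between these libraries.

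The first comparison asked how promoter contacts are distributed over distance when cohesin is depleted. Contacts were shorter with auxin. The median distance was 161 ± 5.18 kb (SD, n = 4) in the libraries with auxin and 213 ± 3.84 kb (n = 4) in those without, a difference of -52.1 kb. Contacts at 100 to 500 kb made up 52.0% ± 0.279 of the list with auxin and 63.1% ± 0.742 without, while contacts under 100 kb made up 34.2% ± 0.967 and 22.8% ± 0.888. These differences of -11.2 and 11.4 points were -20.9 and 20.8 at a score of at least 10. In listed contacts the share at 500 kb to 2 Mb differed by less than its spread, with 13.5% ± 0.702 and 13.7% ± 0.286 (two-sided exact permutation test, p = 0.714). That difference of -0.176 points was -0.624 in shares of reads (exact permutation p = 0.0857). The difference in median distance was present without amanitin (-54.8 kb) and with it (-49.5 kb), in library sets that share no sample. For the median and both shorter ranges every library with auxin lay beyond every library without (two-sided exact permutation test of 4 against 4, p = 0.0286, the smallest this design allows). After Benjamini-Hochberg adjustment over the 40 comparisons of this family that value was 0.0762, so no distance measure passed the correction. Even with every auxin comparison at the smallest p, none could have passed unless amanitin comparisons had reached it as well. The correction therefore cannot decide whether these differences exceed chance.

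**Figure D1:**
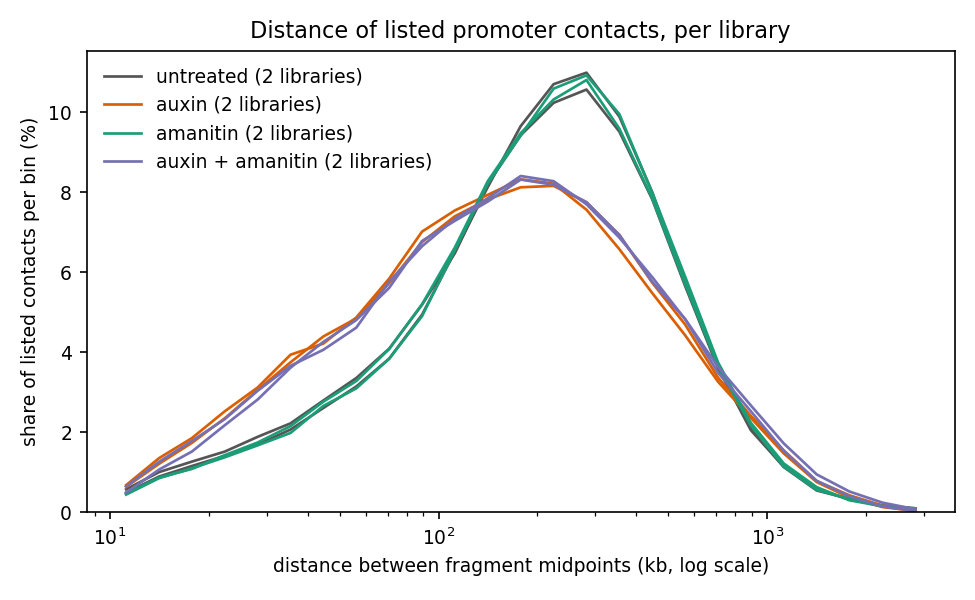
Share of listed contacts (%, y axis) per bin of the distance between fragment midpoints (kb, logarithmic x axis), 1 line per library, coloured by group. The 4 libraries with auxin hold 34.2% of contacts under 100 kb on average and the 4 without hold 22.8%.

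**Figure D2:**
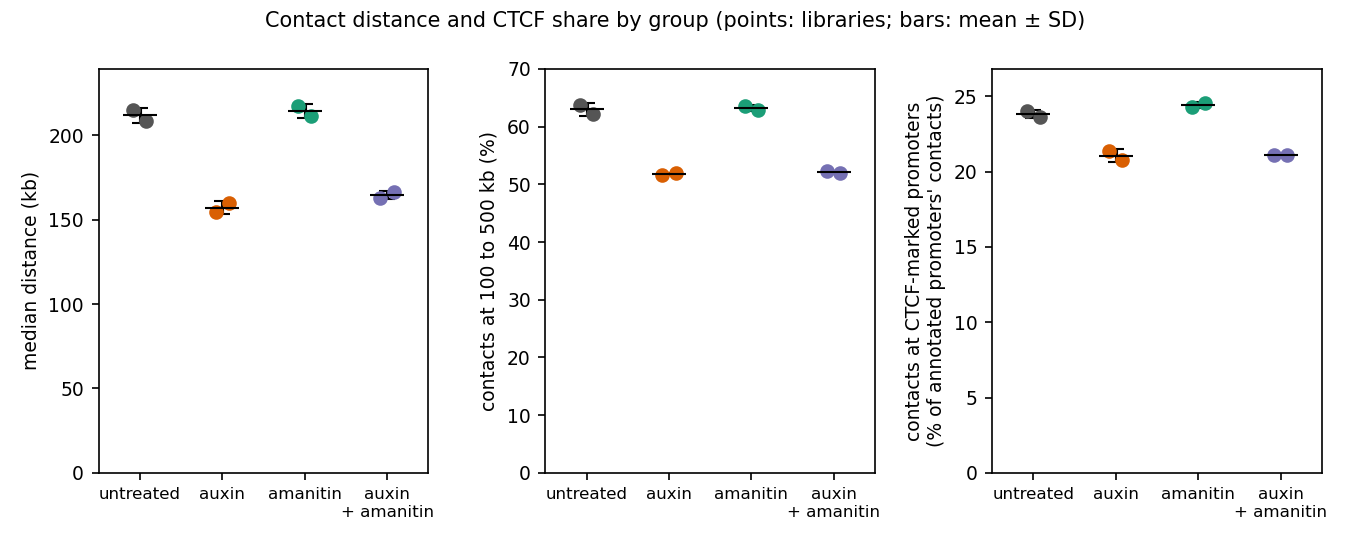
Median contact distance (kb), share of contacts at 100 to 500 kb (%) and share of annotated promoters' contacts that start at CTCF-marked promoters (%), by group; points are libraries, horizontal lines with bars are means ± SD of 2 libraries. Both groups with auxin lie lower in the 3 panels.

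The shift covered each class of fragment examined. Contacts with active enhancers had a median distance of 142 ± 4.17 kb (SD, n = 4) with auxin and 178 ± 2.83 kb without. For contacts whose other end carries a gene name the medians were 110 ± 5.57 and 154 ± 1.61 kb. That gene was not compared with the gene of the bait, so contacts within 1 gene can be among them. Promoters marked in the files as bound by CTCF, the factor at which cohesin-held loops are anchored, had medians of 157 ± 5.38 and 208 ± 1.23 kb, and promoters without the mark 164 ± 4.80 and 216 ± 3.72 kb. For active promoters the medians were 159 ± 4.51 and 208 ± 3.43 kb, and for inactive promoters 170 ± 8.52 and 230 ± 2.72 kb. Promoters with the CTCF mark contributed 21.1% ± 0.242 of the annotated promoters' contacts with auxin and 24.1% ± 0.402 without, and the difference of -3.04 points was -9.28 at a score of at least 10. Each of these differences had p = 0.0286 in the two-sided exact permutation test (0.0762 after adjustment). Contacts whose other end carries a gene name made up 17.3% ± 0.373 with auxin and 18.4% ± 1.45 without (exact permutation p = 0.286). That difference of -1.04 points was 8.86 at a score of at least 10 (exact permutation p = 0.0286). Active enhancers took part in 5.19% ± 0.891 of contacts with auxin and 5.68% ± 0.387 without (exact permutation p = 0.343). Without replicate 5 of the combined treatment this difference was -0.921 points (exact permutation p = 0.0286), and at a score of at least 10 it was -1.75 (exact permutation p = 0.143).

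The second comparison asked which promoters lost or gained contacts of loop length, 100 kb to 2 Mb, with auxin alone. At HOXB4, a homeobox gene of body patterning (chromosome 17, 46654256 to 46656390, hg19), long-range reads fell from 229 and 296 in the untreated libraries to 23 and 20 with auxin, a log2 change of -2.83 ± 0.36 (SE, n = 2 per group; edgeR adjusted p = 0.000485). Falls were also found at MSX2 (-3.29 ± 0.52), a homeobox gene, GADD45G (-3.37 ± 0.73), a stress response gene, HOXA4 (-3.29 ± 0.67) and PAX2 (-2.17 ± 0.30), a paired box regulator of kidney development (chromosome 10, 102504326 to 102506965), whose reads went from 420 and 594 to 71 and 59. At CCND1, which encodes cyclin D1 (chromosome 11, 69455849 to 69456255), 35 and 65 long-range reads were listed in untreated cells and 0 and 2 with auxin (edgeR adjusted p = 0.00475). At LIPG, encoding endothelial lipase, 67 and 51 reads stood against 2 and 0 (edgeR adjusted p = 0.00733).

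No long-range contact was listed with auxin at the promoters of UNG, the uracil DNA glycosylase, LRRC71 and AK3, where untreated libraries held 24 and 17, 26 and 13, and 22 and 14 reads, so no fold is given for them. Fewer promoters rose. ACSL5, a fatty acid CoA ligase (chromosome 10, 114133099 to 114135734), went from 43 and 63 to 134 and 178 reads (2.31 ± 0.33, edgeR adjusted p = 0.00112). The others were C8orf87 (2.77 ± 0.55), SYT10 (2.60 ± 0.60), TMEM255B (2.46 ± 0.53), RUNX1T1 (2.18 ± 0.49), MED28 (2.12 ± 0.46), ANKFN1 (2.10 ± 0.45) and AQP9, a water and glycerol channel with 3 and 0 reads in untreated and 25 and 13 with auxin. Library factors from contacts under 100 kb moved the median of all promoters from 0.0126 to -0.82. After this common shift ANKFN1 (1.27), MED28 (1.29), RUNX1T1 (1.33), SYT10 (1.76) and TMEM255B (1.63) no longer passed the threshold (edgeR adjusted p 0.0527 to 0.0868). With a lower bound of 200 kb in place of 100 kb, 11 of the 21 named promoters still measured no longer passed: ACSL5 (0.06, adjusted p = 0.981), PAX2 (-0.93, 0.489), HOXC5 (-0.46, 0.801), C8orf87 (2.74, 0.0566), SYT10 (2.73, 0.0785), RUNX1T1 (1.94, 0.103) and MED28 (2.82, 0.266; edgeR). The other 4 were GADD45G (33 and 40 reads against 0 and 2), TMEM255B (3 and 0 against 18 and 6), UNG (22 and 15 against 0 and 0) and AK3 (22 and 14 against 0 and 0). The change nearly vanished at ACSL5 and was smaller at PAX2 and HOXC5, while at C8orf87 and SYT10 it was about as large as at 100 kb. At MED28 the replicates overlapped, with 9 and 0 reads in untreated cells against 6 and 36 with auxin, so its value rests on auxin replicate 2. The Wald test of DESeq2 passed 10 of the 22 named promoters, gave no adjusted p to 11, and gave 0.0529 to YWHAZ. At a score of at least 10 HOXB4 (29 and 24 reads against 0 and 0) and YWHAZ (20 and 26 against 0 and 0) did not pass among 5 still measured, and with DESeq2 size factors LRRC71 did not. Only ACSL5 and HOXB4 passed without each library in turn.

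Of 12243 promoters tested for long-range reads, 99 passed an adjusted p of 0.05 for auxin against untreated cells, 91 lower and 8 higher (edgeR quasi-likelihood test, Benjamini-Hochberg). The count was 13 without auxin replicate 2, 23 without auxin replicate 1, 27 and 47 without untreated replicates 2 and 1, 46 and 50 without amanitin replicates 3 and 4, and 209 and 229 without replicates 5 and 4 of the combined treatment. With library factors from contacts under 100 kb, which let the whole long-range class move, 1639 promoters passed, 1636 lower and 3 higher. The median over all promoters was then -0.82, where the TMM factors gave 0.0126. Contacts under 100 kb held 52.5 and 52.9% of listed reads with auxin and 36.0 and 38.5% in untreated cells. These factors therefore carry the distance shift into the long-range values, and a gain of short contacts cannot be told from a long-range loss.

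Of 36 promoters of the HOX clusters, homeobox genes that set position along the body axis, 30 lay below 0 in long-range reads with auxin, with a median log2 change of -0.95. The set passed limma camera with a preset correlation (adjusted p = 5.31e-08) but not with an estimated one (adjusted p = 0.0800), and fry gave an adjusted p of 0.0132. Of its members 4 fell past the threshold over all promoters and 14 when adjusted over the list alone, among them HOXB8 (-2.39 ± 0.52) and HOXC5 (-1.80 ± 0.38), the latter not with a lower bound of 200 kb. Under factors from contacts under 100 kb the HOX median was -1.79 and 20 members fell, against the shift of -0.82 of all promoters. In the cells given amanitin, auxin had the same direction at these genes, with a median of -1.23, 6 falls over all promoters and 16 when adjusted over the list alone (camera adjusted p = 3.04e-08, 0.0800 with an estimated correlation).

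The third comparison repeated the auxin contrast in the presence of amanitin, with 4 libraries that the first contrast did not use. SOCS1, an inhibitor of cytokine signalling (chromosome 16, 11349722 to 11350870), went from 271 and 198 long-range reads with amanitin to 7 and 16 with both treatments (-3.95 ± 0.45, edgeR adjusted p = 0.000284). Falls were also found at STAM2, an endosomal sorting adaptor gene (-3.64 ± 0.45; chromosome 2, 153030564 to 153032334), CCND1 (-3.81 ± 0.73), HOXA4 (-3.10 ± 0.64), PDGFRA, which encodes a growth factor receptor (-3.00 ± 0.41), HOXA6 (-2.35 ± 0.52), HOXB4 (-2.03 ± 0.34) and PAX2 (-1.96 ± 0.30). MOB3B (-3.22 ± 0.73) and MCOLN3 (-3.13 ± 0.72) fell as well. HOXA7 went from 52 and 37 reads to 0 and 2, ACO1, the cytosolic aconitase, from 25 and 46 to 0 and 2, and RRBP1 from 24 and 37 to 3 and 0. Among rises were ACSL5 (2.85 ± 0.35, edgeR adjusted p = 0.000357), ABRA (2.86 ± 0.59), PCK1, which encodes a gluconeogenic enzyme (3.10 ± 0.68), TNP1 (3.41 ± 0.81) and PTAR1, where 3 and 0 reads stood against 16 and 20. NEURL1 (2.36 ± 0.54), CCL2 (2.84 ± 0.67), OR51E2 (2.61 ± 0.59), ZNF230 (1.60 ± 0.33) and ZNF224 (1.25 ± 0.30) rose too. They did not pass with factors from contacts under 100 kb, which moved the median of all promoters to -0.76 and these promoters to 1.57, 2.07, 1.82, 0.79 and 0.45. With a lower bound of 200 kb, 14 of the 22 named promoters still measured no longer passed: ACSL5 (1.54, adjusted p = 0.362), PAX2 (-0.28, 0.899), HOXA4 (-3.30, 0.0982), HOXA6 (-2.24, 0.0823), CCL2 (2.76, 0.109), OR51E2 (2.69, 0.123), PCK1 (2.79, 0.150), TNP1 (3.27, 0.123), ZNF224 (1.14, 0.279) and ZNF230 (1.31, 0.227; edgeR). The other 4 were MOB3B (22 and 8 reads against 2 and 2), MCOLN3 (17 and 17 against 0 and 0), RRBP1 (24 and 22 against 3 and 0) and PTAR1 (0 and 0 against 10 and 7). The Wald test of DESeq2 passed 8 of the 23 named promoters and gave no adjusted p to the other 15, CCND1 among them. At a score of at least 10 ACSL5 (5 and 0 reads against 8 and 28), HOXB4 (5 and 19 against 0 and 0), STAM2 (6 and 0 against 0 and 0) and ZNF224 (24 and 10 against 9 and 28) did not pass among 7 still measured. Only ACSL5, PDGFRA, SOCS1 and STAM2 passed without each library in turn.

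In this contrast 126 promoters passed, 111 lower and 15 higher, and the count was 26 without amanitin replicate 3 and 20 without amanitin replicate 4. With factors from contacts under 100 kb it was 1527, of which 8 were higher. The log2 changes of the 2 auxin contrasts, which share no library, had r = 0.405 and rho = 0.415 across 12243 promoters, which are not independent replicates, and the same sign at 64.8%. Of the 91 and 111 promoters that fell, 47 fell in both, where independent lists would share 0.825, and 90 of the 91 had the same sign in the contrast with amanitin. Of 8 and 15 that rose, 1 rose in both. Both contrasts come from the same fit, with a common filter and estimate of spread per promoter, so their calls can coincide more often than independent lists.

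**Figure D3:**
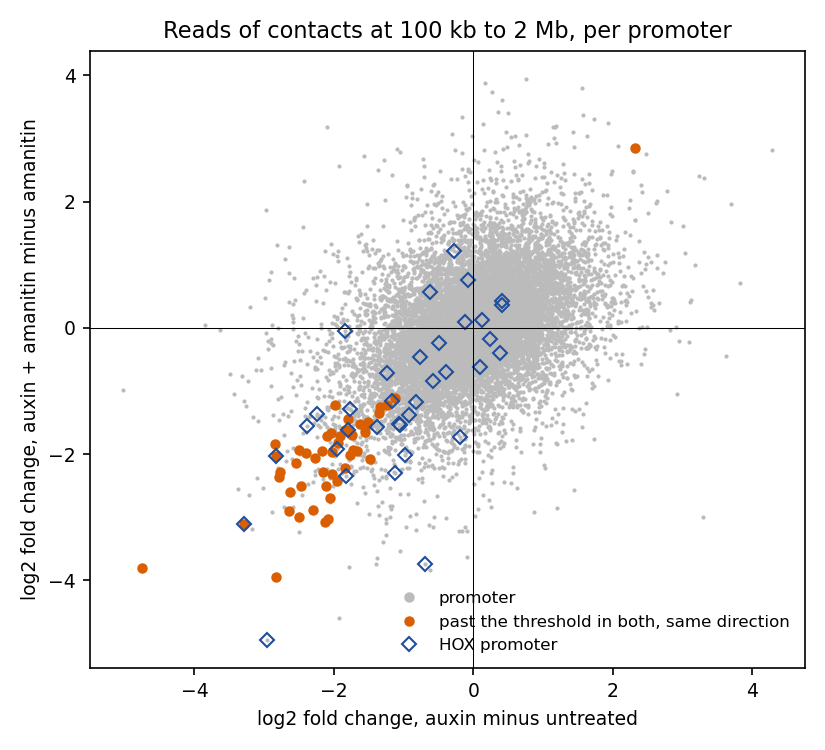
Log2 fold change of long-range reads (100 kb to 2 Mb) per promoter, auxin minus untreated (x axis) against both treatments minus amanitin (y axis), for 12168 promoters; 75 with no listed read in some group are not drawn. Filled circles passed the threshold in both contrasts in the same direction (47 fell, 1 rose), and open diamonds are 35 HOX promoters, 25 of them below 0 on both axes.

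Against untreated cells, promoters passed with the combined treatment in long-range reads as well. Falls included SOCS1 (-3.73 ± 0.45, edgeR adjusted p = 0.000667), STAM2 (-3.52 ± 0.45), ARMC12 (-3.15 ± 0.52), CHMP1B (-3.06 ± 0.66), HOXB4 (-2.44 ± 0.35), HOXC5 (-1.86 ± 0.38) and KRT19, an epithelial keratin gene (-1.66 ± 0.40). At HOXA5, 26 and 23 reads were listed in untreated cells and no long-range contact with both treatments. Rises included DCBLD2 (2.90 ± 0.44), RALGAPB (2.69 ± 0.58) and the RNA helicase gene DDX1 (3.26 ± 0.72), with ARGLU1 at 2 and 2 reads in untreated and 12 and 29 with both treatments. FERMT1 (2.42 ± 0.57), OR6K3 (2.09 ± 0.49), SPINK13 (3.27 ± 0.80), TMEM255B (2.24 ± 0.53), and the zinc finger genes ZNF225 (87 and 67 reads against 109 and 184) and ZNF224 (85 and 143 against 132 and 204) passed with TMM factors. They did not pass with factors from contacts under 100 kb, which moved the median of all promoters to -0.73 and these promoters to 1.69, 1.34, 2.55, 1.49, 0.73 and 0.46. With a lower bound of 200 kb, 13 of the 22 named promoters still measured no longer passed: ARMC12 (-1.37, adjusted p = 0.526), KRT19 (-1.68, 0.133), HOXC5 (-0.29, 0.902), PAX2 (-0.18, 0.936), DDX1 (2.47, 0.228), RALGAPB (2.40, 0.336), FERMT1 (1.02, 0.787), OR6K3 (1.8, 0.315), SPINK13 (2.15, 0.507), ZNF224 (1.03, 0.315) and ZNF225 (1.4, 0.162; edgeR). The other 2 were ARGLU1 (2 and 2 reads against 8 and 22) and TMEM255B (3 and 0 against 9 and 24). The Wald test of DESeq2 passed 11 of the 24 named promoters and gave no adjusted p to the other 13. At a score of at least 10 ARMC12 (17 and 38 reads against 0 and 0), DCBLD2 (0 and 4 against 10 and 71), HOXB4 (29 and 24 against 0 and 0), STAM2 (15 and 36 against 0 and 0), ZNF224 (0 and 6 against 9 and 28) and ZNF225 (10 and 0 against 6 and 43) did not pass among 9 still measured. Only ARMC12, HOXB4, PAX2, SOCS1 and STAM2 passed without each library in turn. The HOX median was -1.51, with 5 falls over all promoters and 18 when adjusted over the list alone (camera adjusted p = 9.81e-09, 0.0800 with an estimated correlation). In all 144 promoters passed, 124 lower and 20 higher, and 1404 with factors from contacts under 100 kb, 7 of them higher. Single libraries moved this count to 26 (without untreated replicate 2), 63 (untreated replicate 1), 82 and 85 (amanitin replicates 3 and 4), 95 and 255 (replicates 5 and 4 of the combined treatment).

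The fourth comparison asked what amanitin changed. No promoter passed the threshold for amanitin against untreated cells, in long-range reads (412 of 12243 at an unadjusted p under 0.05, 0 by DESeq2) or in all reads within 2 Mb (479 of 13571, 0 by DESeq2, 3 with edgeR and no filter on low counts). MYC, a target of Wnt signalling in colon carcinoma, had a log2 change of 0.78 ± 0.35 in long-range reads, AXIN2 0.28 ± 0.43 and EGR1, an immediate early gene, 0.08 ± 0.59. Immediate early genes as a list had a median of 0.20 over 14 promoters (limma camera adjusted p = 0.234). Nor did a promoter pass for both treatments against auxin alone (554 and 667 at an unadjusted p under 0.05 in long-range and all reads; DESeq2 14 in all reads, 0 in long-range reads) or for the interaction of the treatments (458 and 461). Without replicate 4 of the combined treatment, 5 promoters passed in long-range reads and 4 in all reads for both treatments against auxin.

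The median contact distance was 189 ± 28.7 kb (SD, n = 4) with amanitin and 184 ± 31.8 kb without (two-sided exact permutation test, p = 0.571), each set holding 2 libraries with auxin and 2 without. The difference was 2.39 kb without auxin and 7.69 kb with auxin, where the libraries with amanitin (162.94 and 166.50 kb) lay above those without (154.30 and 159.75 kb), a comparison of 2 against 2 that cannot give an exact p under 0.05. The difference of 5.04 kb over all 8 libraries ranged from -5.00 to 15.3 kb without 1 library and was negative without either auxin or either amanitin library, where the sets hold unequal numbers of libraries with auxin. Contacts at 500 kb to 2 Mb made up 14.0% ± 0.374 with amanitin and 13.3% ± 0.372 without (exact permutation p = 0.0286, 0.0762 after adjustment). That difference of 0.690 points was 0.609 in shares of reads (exact permutation p = 0.143), and 0.370 without auxin and 1.01 with it. It was 0.512 without auxin replicate 1 (exact permutation p = 0.0857), 0.703 without auxin replicate 2 (0.0857), 0.638 without amanitin replicate 3 and 0.538 without replicate 5 of the combined treatment (0.0571 each). Active promoters had a median log2 change of 0.01 in long-range reads and inactive ones -0.13 (camera adjusted p = 0.0118, adjusted p = 0.0282 with an estimated correlation), and in all reads 0.03 and -0.17 (0.00258 and 0.0238). For both treatments against auxin the same medians were 0.04 and -0.10 in long-range reads (camera adjusted p = 0.113, 0.0830 with an estimated correlation) and 0.07 and -0.09 in all reads (0.0200 and 0.0495). All libraries with amanitin carry replicate numbers 3 to 5 and those without carry 1 and 2, so the treatment and the replicate set cannot be told apart. For active enhancers the share differed by 0.529 points between libraries with and without amanitin (exact permutation p = 0.314), and by 0.939 without replicate 4 of the combined treatment (exact permutation p = 0.0286).

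In reads of all contacts within 2 Mb, fewer promoters passed. For auxin against untreated cells no promoter did (edgeR; 1181 of 13571 at an unadjusted p under 0.05, 167 by DESeq2), while 81 and 66 passed without replicates 4 and 5 of the combined treatment. For both treatments against amanitin 16 fell and none rose. They included STAM2 (-3.78 ± 0.49, edgeR adjusted p = 0.00494), COL1A1, a fibrillar collagen gene (-2.09 ± 0.27), PDGFRA (-3.08 ± 0.46), ARMC12 (-2.94 ± 0.47), CEMIP, a hyaluronan-binding protein gene (-2.92 ± 0.49), SOCS1 (-2.87 ± 0.47), WNT7A (-2.62 ± 0.43), NTMT1 (-2.25 ± 0.41) and C19orf24 (-2.24 ± 0.34). None passed without amanitin replicate 3 or without amanitin replicate 4, and 227 did without replicate 4 of the combined treatment. For both treatments against untreated cells 27 fell and 6 rose, the rises being AQP9 (3.58 ± 0.66), VTI1A/ZDHHC6 (3.24 ± 0.49), NASP (2.95 ± 0.56), EFCAB3 (2.88 ± 0.57), C8orf44/C8orf44-SGK3/VCPIP1 (2.66 ± 0.41) and MIA3 (2.29 ± 0.45). Falls outside those already named included HAGHL/CCDC78 (-3.04 ± 0.54) and RNF224 (-2.62 ± 0.49). That count of 33 was 310 and 13 without replicates 4 and 5 of the combined treatment, 1 and 4 without untreated replicates 2 and 1, 5 without amanitin replicate 3, 5 without amanitin replicate 4, and 19 and 9 without auxin replicates 1 and 2. In neither contrast did a named promoter pass without each library in turn. At a score of at least 10, 1 of the 10 named promoters still measured passed against untreated cells and 1 of 8 against amanitin. Most of the others had reads on 1 side alone. Against untreated cells (untreated first) these were ARMC12 (17 and 38 against 0 and 0), CEMIP (21 and 8 against 0 and 0), RNF224 (24 and 48 against 0 and 0), SOCS1 (22 and 39 against 0 and 0), STAM2 (15 and 36 against 0 and 0), WNT7A (30 and 52 against 0 and 0), MIA3 (0 and 0 against 15 and 50), NASP (0 and 0 against 0 and 17) and C8orf44/C8orf44-SGK3/VCPIP1 (0 and 0 against 0 and 18). Against amanitin they were ARMC12 (38 and 8 against 0 and 0), CEMIP (14 and 15 against 0 and 0), NTMT1 (72 and 68 against 0 and 0), SOCS1 (65 and 46 against 0 and 0), STAM2 (6 and 0 against 0 and 0) and WNT7A (36 and 7 against 0 and 0), while C19orf24 had 29 and 33 against 10 and 0. AQP9, EFCAB3, HAGHL/CCDC78 and NASP were given no adjusted p by DESeq2 against untreated cells, and EFCAB3 did not pass with contacts over 20 kb (2.19, edgeR adjusted p = 0.148).

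Promoters chosen for naming whatever their result did not pass in either test or any contrast. In long-range reads with auxin the log2 change was -1.1 ± 0.47 at AXIN2, -0.79 ± 0.44 at CDX2, an intestinal homeobox gene, 0.66 ± 0.60 at CDX1, 0.07 ± 0.36 at MYC, -0.14 ± 0.48 at SOX9, 0.07 ± 0.48 at CDKN1A, 0.04 ± 0.61 at EGR1, 0.24 ± 0.59 at RAD21 and 0.85 ± 0.56 at the fragment shared by ZBTB4 and POLR2A. With factors from contacts under 100 kb, which moved the median of all promoters to -0.82 for auxin and to -0.76 for both treatments against amanitin, AXIN2 (-1.96) and CDX2 (-1.61) passed for auxin, also in the other contrasts that add auxin, and MYC passed (-1.18) for both treatments against amanitin. These calls include the common shift, which cannot be told from a gain of contacts under 100 kb. AXIN2 also passed for auxin with a lower bound of 200 kb (-3.10, edgeR adjusted p = 0.0337). The auxin values of CDX1 (-0.20), MYC (-0.75), CDKN1A (-0.76), EGR1 (-0.79) and RAD21 (-0.60) lay below 0 with factors from contacts under 100 kb, as the common shift alone would bring. KLF5 was listed but had too few reads to be tested.

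Replication histone genes, olfactory receptor genes and zinc finger genes of chromosome 19, families that lie in tandem arrays, had higher long-range read shares with auxin. Their medians were 0.89 (33 promoters), 0.53 (160) and 0.41 (144), which went to 0.07, -0.32 and -0.38 with factors from contacts under 100 kb, where all promoters had a median of -0.82. No member passed singly, and the camera adjusted p of 3.35e-05, 3.89e-05 and 0.000560 became an adjusted p of 0.554, 0.208 and 0.554 with an estimated correlation. In all reads Wnt targets had a median of -0.40 (camera adjusted p = 0.0392, adjusted p = 0.814 with an estimated correlation). In that test 9 pairs of list and contrast passed with the preset correlation and 0 with an estimated one.

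The other lists did not pass camera in long-range reads with auxin, the lowest adjusted p being 0.0830 for neuronal markers (median 0.52, 15 promoters). Medians were -0.18 for colon epithelium, -0.30 for Wnt targets, where CCND1 fell, 0.02 for immediate early genes, -0.06 for housekeeping genes, where YWHAZ, a 14-3-3 adaptor, fell by 1.91 ± 0.42 on the log2 scale, and -0.07 for cohesin and CTCF genes. They were 0.17 for Mediator subunits, 0.22 for Pol II subunits, -0.08 for developmental transcription factors, 0.15 for blood cell markers and 0.20 for hepatocyte markers. For p53 targets (median 0.00128, mean -0.24), muscle and fibroblast markers (0.03 and -0.28), immediate early genes (0.02 and -0.02) and clustered protocadherins (-0.03 and 0.05) the median and the mean had opposite signs. PDGFRA was the muscle and fibroblast marker that fell (-2.50 ± 0.42). CTCF-marked promoters had a median of -0.18 against 0.06 for the other annotated promoters (camera adjusted p = 0.0118, 0.00803 with an estimated correlation), and -0.17 against 0.09 with amanitin present. Active promoters had -0.05 and inactive ones 0.12 for auxin (camera adjusted p = 0.101, 0.0810 with an estimated correlation), and -0.02 and 0.20 with amanitin present (camera adjusted p = 0.0222, 0.0395 with an estimated correlation). In all reads the medians were -0.05 and 0.11 for auxin (0.0435 and 0.0705), and 0 and 0.21 with amanitin present (0.0200 and 0.0495).

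Shared contacts were compared between libraries to set treatment differences against replicate differences. Replicates of 1 group shared 2.77% of the contacts in their union on average, libraries alike in auxin but not in amanitin 2.80%, and libraries unlike in auxin 2.12%. The difference of 0.667 points between libraries alike and unlike in auxin was the largest among the 35 splits of the 8 libraries into 4 and 4 (exact permutation p = 0.0286). At the listed score the libraries without auxin carried it, since their pairs shared 3.14 to 3.6%, while pairs with auxin in both shared 2.01 to 2.64%, a range that overlaps the 1.83 to 2.49% of pairs unlike in auxin. At a score of at least 10 the ranges were 4.04 to 4.92%, 2.71 to 4.54% and 1.76 to 3.12%, with the difference at 1.52 points. Both replicates listed 3.30% of the union in untreated cells, 2.35% with auxin, 3.42% with amanitin and 2.01% with both. Of the 213 pairs of fragments listed in every library, 140 had enough reads, and none passed in any contrast (edgeR; 7 at an unadjusted p under 0.05 for auxin and 3 for amanitin against untreated cells; 0 by DESeq2). For both treatments against untreated cells 1 pair passed without amanitin replicate 3, and 1 without replicate 4 of the combined treatment.

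The last comparisons asked which Mediator subunits ES cells and T cells need for growth. In ES cells sgRNAs against Med30, a head subunit, had a median log2 change of -2.75 ± 0.23 (SD, n = 4 replicates) from day 0 to day 21, relative to total counts, in which the control sgRNAs stood at 0.98 ± 0.14. ES cell values printed with an SD are means of the 4 replicate medians. The fit over all replicates gave medians of -3.13 for Med30 and -2.70 for Med10, in the opposite order to the replicate means. Large losses were also found for the head subunits Med6 (-2.57 ± 0.44) and Med8 (-1.87 ± 0.34), the middle subunits Med10 (-3.37 ± 1.83), Med14 (-1.88 ± 0.17), Med26 (-1.36 ± 0.22) and Med4 (-1.32 ± 0.48), the tail subunit Med15 (-1.72 ± 0.55) and the kinase module subunit Med12 (-1.47 ± 0.36). Smaller values were measured for Med27 (-1.18 ± 0.47), Med18 (-1.12 ± 0.44), Med19 (-0.91 ± 0.32), Med21 (-0.87 ± 0.27), Med17 (-0.80 ± 0.23), Med7 (-0.77 ± 0.32), Med28 (-0.60 ± 0.42), Med22 (-0.56 ± 0.27), Med29 (-0.55 ± 0.37), Med25 (-0.27 ± 0.28) and Med20 (-0.21 ± 0.22).

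The tail subunit Med23 (1.35 ± 0.28) stood above the control sgRNAs, and Med16 (0.94 ± 0.28) differed from them by less than its SD. Values between 0 and the control were measured for the head subunit Med11 (0.07 ± 0.36), the tail subunit Med24 (0.50 ± 0.33), the middle subunits Med1 (0.66 ± 0.25), Med9 (0.51 ± 0.23) and Med31 (0.37 ± 0.21), and the kinase module genes Med13l (0.88 ± 0.19), Cdk19 (0.80 ± 0.12), Med12l (0.62 ± 0.32), Med13 (0.60 ± 0.26), Cdk8 (0.31 ± 0.21) and Ccnc (0.12 ± 0.09). These values lie above 0 relative to total counts, and their medians lie below 0 relative to the control sgRNAs. Where sgRNAs of a gene went apart, the mean over them differed from the median of the fit. Med20 had a mean of -1.85 and a median of -0.13, with 1 sgRNA at -7.99 and another at 0.87. For the others mean and median were -0.87 and 0.11 for Med11, -1.42 and -0.53 for Med28, -1.56 and -0.78 for Med17, -0.39 and -0.17 for Med25, and -1.38 and -0.92 for Med18. The mean was also lower by over 1 SD for Med12 (-2.02), Med4 (-1.71) and Med26 (-1.58), and higher for Med30 (-2.36), so the order of genes holds for medians alone. The median of all sgRNAs was -0.17 relative to total counts, -1.17 with factors from the control sgRNAs and 0.13 with the median sgRNA as the scale. Head sgRNAs fell most often, 36 of 57 with 7 that rose, then middle sgRNAs (19 fell and 9 rose of 38), tail (5 and 11 of 22) and kinase module (4 and 19 of 31), while all 4 control sgRNAs rose. With factors from the control sgRNAs the falls were 49, 29, 10 and 12. Over all 152 sgRNAs 64 fell and 50 rose (edgeR, adjusted p under 0.05), and 100 fell and 1 rose with factors from the control sgRNAs.

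**Figure D4:**
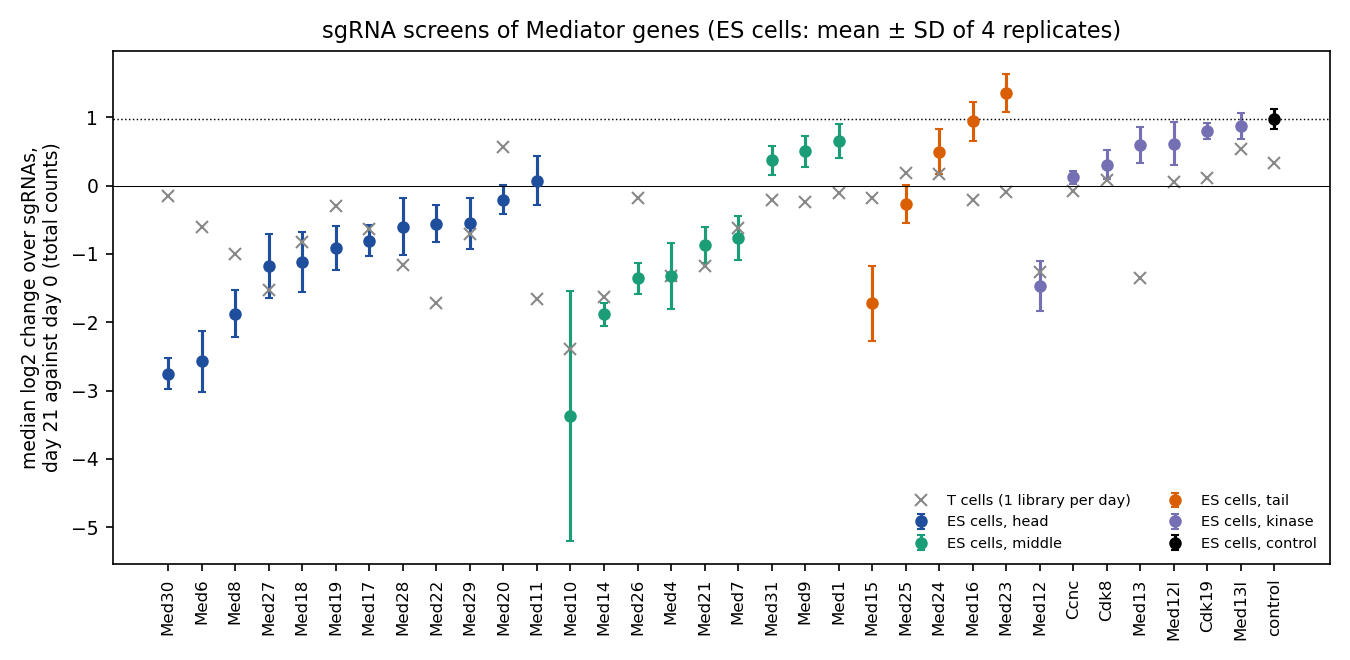
Median log2 change over the sgRNAs of each Mediator gene between day 0 and day 21, relative to total counts (y axis), by gene and module (x axis). Filled points with bars are the mean ± SD of 4 ES cell replicates, crosses are the T cell screen with 1 library per day, and the dotted line is the ES cell control level of 0.98.

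In T cells, with 1 library at each day and so no replicate check, the lowest gene medians were those of Med10 (-2.40, percentile 0.230 among 10000 random sets of as many sgRNAs), Med22 (-1.72), Med11 (-1.65), Med14 (-1.62), Med27 (-1.53), Med13 (-1.35), Med4 (-1.32) and Med12 (-1.26), with the control sgRNAs at 0.34. The highest were Med20 (0.56, percentile 97.8) and Med13l (0.53). Med30 had -0.15 and Med6 -0.61. Across genes, which are not independent replicates, the medians of the screens had r = 0.464 and rho = 0.484. The ES cell median of the fit (-3.13 for Med30, -2.53 for Med6, -1.68 for Med15, 0.69 for Med13, 0.11 for Med11 and -0.45 for Med22) minus the T cell median was -2.99 for Med30, -1.93 for Med6 and -1.51 for Med15, and 2.04 for Med13, 1.76 for Med11 and 1.27 for Med22. Relative to the control sgRNAs of each screen these differences were -3.65, -2.59 and -2.17, and 1.37, 1.1 and 0.61. No gene passed a sign-flip test over its sgRNAs (exact permutation, lowest Benjamini-Hochberg adjusted p = 0.375 over the 33 genes). That test cannot give a p below 0.125 with 4 sgRNAs, 0.0625 with 5 or 0.03125 with 6. After adjustment over the 33 genes none could have passed, so the test cannot decide whether the screens differ.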

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

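All tests of explanations in this part were chosen only after the result was seen. Among 34 groups of 4 ES cell replicates, 1 stood out at a level that chance gives in about 1 group in 20: replicate 4 of Cdk8, with a gene median of 0.628 and a gap to the nearest replicate that, as a share of the range, exceeds Dixon's critical value.

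For 7 genes all ES cell replicates had a gene median above 0 while the single T cell value lay below 0, a difference between cell types that was not tested by this comparison. The ES cell minus T cell differences (log2) were 2.04 for Med13, 1.47 for Med23, 1.22 for Med16, 0.822 for Med9, 0.731 for Med1, 0.505 for Med31 and 0.186 for Ccnc. Relative to the control sgRNAs of each screen, the differences were 1.37, 0.802, 0.558, 0.157, 0.0661, -0.160 and -0.479 in the same order, so those of Med31 and Ccnc changed sign. On that scale 2 of the 7 genes keep opposite signs, Med23 (0.381 in ES cells and -0.421 in T cells) and Med16 (0.00846 and -0.550). The ES cell value of Med16 lay within its SD of 0.28 of the control. In T cells the 4 control sgRNAs themselves ranged from -0.494 to 1.13.

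A shared batch is a candidate technical explanation for such differences. Replicate 4 and the T cell screen have the same number of rows with the gene name in upper case (16, against 44 in each of the other replicates). They also have a day 0 correlation of 0.780 with each other, where the other replicates have 0.640 to 0.677 with the T cells. The tables argue against a shared batch as the whole cause: replicate 4 correlated less well with the T cells than with the other ES replicates, by a difference of -0.191 in r across sgRNAs. The r of replicate 4 with the T cells (0.578) was still the highest of the 4 replicates (0.443 to 0.508 in the others) and its r with the other ES replicates the lowest (0.741 to 0.808). At day 0 its mean correlation with the other ES libraries was 0.779, where replicates 1 to 3 had 0.840 to 0.867. A part of the difference from a shared batch therefore stays open. Spread between the sgRNAs of a single T cell screen cannot be told apart from a difference between the cell types. The exact sign-flip tests (lowest adjusted p = 0.375) could not pass for any gene after adjustment. Their smallest possible p is 0.125 with 4 sgRNAs and 0.03125 with 6. A need for different Mediator subunits in the 2 cell types stays open and untested.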

How the results depend on the processing

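Tests chosen only after the result was seen are marked as added here. The cause of a change was not tested unless stated.
Counts of promoters are given as called, with rises and falls after them. The test of all contacts without a filter gave 102 (38 and 64) for auxin, 3 for amanitin, 188 (68 and 120) for both treatments against untreated, 165 (64 and 101) against amanitin, 2 against auxin and 1 for the interaction, and the long-range test 270 (46 and 224), 307 (54 and 253) and 307 (55 and 252) for the 3 contrasts that add auxin and 1 against auxin. DESeq2 gave 167 (51 and 116), 270 (80 and 190), 183 (41 and 142) and 14 in all contacts, and 218 (28 and 190), 250 (28 and 222) and 235 (21 and 214) in long-range reads. A replicate block for untreated and auxin gave 173 (70 and 103) and 323 (72 and 251). Across promoters the deviations of same-numbered libraries from their group means had correlations of 0.0451 and 0.00603. With 2 libraries per group this is a single correlation per test, so it cannot decide whether replicate numbers pair the libraries. The same 4 libraries without a block (added) gave 30 in all contacts. An additive model (added) gave 298 (96 and 202) and 658 (157 and 501) for auxin, with 5 residual degrees of freedom, and 0 for amanitin (705 and 552 at an unadjusted p under 0.05).
A score of at least 10 left 2 for each contrast of both treatments with untreated or amanitin in all contacts, and 15 (auxin), 13 (both against untreated) and 18 (both against amanitin) in long-range reads. The contact test was not run at that score, with 3 pairs listed in all libraries. Contacts over 20 kb gave 3 for auxin. A bound of 200 kb gave 75 and 55 for both treatments against untreated and amanitin. Factors from contacts under 100 kb gave 1639, 1404 and 1527 for the contrasts that add auxin, with median shifts of -0.82, -0.73 and -0.76. Offsets by distance gave 1 pair of fragments for both treatments against untreated.
Leaving out 1 library, the counts ranged in all contacts from 0 to 81 (auxin), 1 to 310 (both against untreated), 0 to 227 (both against amanitin) and 0 to 4 (both against auxin), and in long-range reads from 13 (without auxin replicate 2) to 229, 26 to 255, 20 to 177 and 0 to 5. The highest counts came without replicate 4 of the combined treatment. Pairs of fragments ranged from 0 to 1 for both treatments against untreated and against auxin. A group left with 1 library is assumed to vary like the others. The counts for amanitin and the interaction stayed at 0.
The difference in median distance with auxin kept its direction under every setting run (-68.7 to -49.9 kb); its exact p of 0.0286 is the smallest the design allows and says no more than that the groups did not overlap. The amanitin difference at 500 kb to 2 Mb, 0.690 points, was 0.609 in reads and 0.840 with equal numbers of contacts (added), and 0.512 to 0.794 without 1 library. Without 1 library the enhancer share ranged from -0.921 to -0.250 for auxin and 0.268 to 0.939 for amanitin, and at a score of at least 10 it was -1.75 and 1.21. Differences that did not pass also changed sign. For amanitin the ranges without 1 library were -5.00 to 15.3 kb for the median distance, and in points -3.27 to 1.12 under 100 kb, -1.66 to 2.46 at 100 to 500 kb and -0.262 to 0.895 for the CTCF-marked share, which was -0.945 at a score of at least 10. Without 1 library the sets with and without amanitin hold unequal numbers of libraries with auxin. These ranges therefore take in the auxin difference and cannot show how stable the amanitin difference is. For auxin the share at 500 kb to 2 Mb ranged from -0.472 to 0.0880, and was -0.624 in reads, 0.0360 at a score of at least 10 and 0.126 with equal numbers of contacts (added). The auxin difference in the share of contacts whose other end carries a gene name, -1.04 points, was 8.86 at a score of at least 10 and -1.16 in reads. The class medians of distance kept their direction for auxin under every setting run. The 9 list and contrast pairs called became 0 with an estimated correlation, and the 12 called in long-range reads became 0 as well.
In the screen 31 genes lay below 0 when scaled to control sgRNAs. Values that reversed there were Cdk19 -0.19, Cdk8 -0.68, control -0.0060, Med1 -0.39, Med12l -0.32, Med13 -0.31, Med13l -0.16, Med24 -0.55, Med31 -0.72 and Med9 -0.40, and Med20 0.17 when scaled to the median sgRNA. Genes without a call in the direction of their median for most of their sgRNAs also changed sign: Ccnc -0.89 and Med11 -0.92 with control scaling, Med25 0.13 with median scaling, and Med11 -0.87 by the mean over sgRNAs and -0.011 without replicate 1 (added). Of the 5 sgRNAs of Med11, 2 fell and 2 rose past the threshold. The scaling moved the median sgRNA from -0.17 to -1.17 (control) and 0.13 (median). Leaving out 1 replicate (added) gave 92 to 109 sgRNAs and 20 to 21 genes below 0. A block (added) gave 111, and the minimum of 30 counts removed no sgRNA. Of the values of single promoters and genes 2333 kept direction and call, 484 no longer passed, 8 newly passed, 53 moved and 170 reversed, 122 of the latter without 1 library. Low recovery of 2-fold changes limits what a count of 0 shows.
Promoters named whatever their result, none of which passed in the tests of the report, changed sign as follows. With a replicate block, all contacts: CDX1 -0.15 and SOX9 -0.073 (auxin). With DESeq2 size factors, all contacts: ZBTB4/POLR2A 0.0044 (both against amanitin). By DESeq2, all contacts: ZBTB4/POLR2A 0.0016 (both against amanitin). At a score of at least 10, all contacts: ZBTB4/POLR2A 0.67 (both against amanitin), ZBTB4/POLR2A 1.58 (both against auxin). Over 20 kb, all contacts: CDKN1A 0.089, CDX1 0.073 and ZBTB4/POLR2A 0.035 (both against amanitin), CDKN1A 0.20 (the interaction). With a replicate block, long-range reads: EGR1 -0.043 (auxin). From 200 kb, long-range reads: EGR1 -0.47 and MYC -0.064 (auxin), CDX1 -0.11 (amanitin), CDKN1A -0.034 (both against untreated), SOX9 -0.17 (both against amanitin), CDKN1A -0.074, CDX1 -0.51, CDX2 0.0700, EGR1 0.29, SOX9 -0.078 and ZBTB4/POLR2A 0.32 (both against auxin), EGR1 0.23 and ZBTB4/POLR2A 0.23 (the interaction). With factors from contacts under 100 kb, long-range reads: CDKN1A -0.76, CDX1 -0.20, EGR1 -0.79, MYC -0.75 and RAD21 -0.60 (auxin), CDKN1A -0.67, MYC -0.33 and ZBTB4/POLR2A -0.44 (both against untreated), CDKN1A -0.62, CDX1 -0.36, SOX9 -0.74 and ZBTB4/POLR2A -0.65 (both against amanitin), EGR1 0.025 (both against auxin). Without 1 library such values ranged as follows. All contacts, auxin: CDX1 -1.44 to 0.79, MYC -0.098 to 0.64, RAD21 -0.47 to 0.16, SOX9 -0.68 to 0.52, ZBTB4/POLR2A -0.21 to 0.17. All contacts, amanitin: AXIN2 -0.24 to 0.99, CDKN1A -0.093 to 0.72, CDX1 -0.046 to 0.46, CDX2 -0.13 to 0.56, RAD21 -0.76 to 0.076, SOX9 -0.31 to 0.14, ZBTB4/POLR2A -1.04 to 0.48. All contacts, both against untreated: CDKN1A -0.28 to 0.50, CDX1 -0.32 to 0.51, EGR1 -0.72 to 1.24, SOX9 -0.36 to 0.61, ZBTB4/POLR2A -0.94 to 0.42. All contacts, both against amanitin: CDKN1A -0.65 to 0.26, CDX1 -0.55 to 0.28, EGR1 -1.36 to 0.60, SOX9 -0.29 to 0.68, ZBTB4/POLR2A -0.86 to 0.94. All contacts, both against auxin: AXIN2 -0.17 to 0.42, CDKN1A -0.0895 to 0.69, CDX1 -0.65 to 1.59, CDX2 -0.58 to 0.31, EGR1 -1.31 to 0.65, SOX9 -0.37 to 0.90, ZBTB4/POLR2A -0.91 to 0.45. All contacts, the interaction: AXIN2 -0.90 to 0.33, CDKN1A -0.46 to 0.44, CDX1 -0.88 to 1.37, CDX2 -0.84 to 0.044, EGR1 -1.96 to 0.0035, SOX9 -0.31 to 0.96, ZBTB4/POLR2A -0.82 to 0.97. Long-range reads, auxin: CDKN1A -0.13 to 0.25, CDX1 -0.12 to 1.28, EGR1 -0.70 to 0.56, MYC -0.29 to 0.52, RAD21 -0.045 to 0.45, SOX9 -1.25 to 0.51. Long-range reads, amanitin: AXIN2 -0.18 to 0.89, CDKN1A -0.57 to 0.24, CDX2 -0.17 to 0.46, EGR1 -0.026 to 0.17, SOX9 -0.41 to 0.10, ZBTB4/POLR2A -1.0 to 0.78. Long-range reads, both against untreated: CDKN1A -0.41 to 0.42, EGR1 -1.42 to 0.71, SOX9 -0.52 to 0.26, ZBTB4/POLR2A -0.016 to 0.68. Long-range reads, both against amanitin: CDKN1A -0.31 to 0.64, EGR1 -1.50 to 0.62, SOX9 -0.40 to 0.38, ZBTB4/POLR2A -0.51 to 1.28. Long-range reads, both against auxin: CDKN1A -0.49 to 0.35, CDX1 -0.20 to 1.06, CDX2 -0.40 to 0.17, EGR1 -1.47 to 0.66, SOX9 -0.58 to 1.17. Long-range reads, the interaction: AXIN2 -0.58 to 0.48, CDKN1A -0.39 to 0.58, CDX1 -0.86 to 0.54, CDX2 -0.59 to 0.053, EGR1 -1.55 to 0.57, SOX9 -0.45 to 1.29, ZBTB4/POLR2A -1.34 to 0.44.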

Other observations

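Of the tests in this part, those of equal numbers of top-scoring contacts, of the replicate set, of the control sgRNAs, of the other splits of the libraries and of mirrored positions, and the counts by CTCF mark, were chosen only after the result was seen. Promoters marked by CTCF held 29 of the annotated promoters called in long-range reads for auxin, among 1229 tested, and the other annotated promoters held 26 among 4365. For both treatments against amanitin the counts were 33 and 28. The share of contacts of 1 library within 5 kb of a contact of the same bait in another was compared with the share when the other ends were mirrored around the bait. Between replicates it was 25.3% against 10.0% mirrored in untreated cells, 25.3% against 9.22% with amanitin, 17.9% against 10.6% with auxin and 15.5% against 8.96% with both treatments. Between libraries alike in auxin and unlike in amanitin the shares were 21.1% and 9.82% on average, and between libraries unlike in auxin 16.1% and 9.16%.

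The shorter contacts with auxin were weighed against 3 technical explanations. With the same number of top-scoring contacts in every library the difference in median distance was -51.2 kb, which argues against the number of listed contacts as its cause. With a score of at least 10 it was -68.7 kb, so its direction held at a stricter cut. That cut also changed the mix of contacts. Those whose other end carries a gene name went from 16.9 to 51.4% in untreated replicate 1 and from 17.3 to 62.7% in auxin replicate 1. Contacts with a score under 5 are not listed, so the stricter cut cannot exclude the score threshold as a cause. Within a replicate set the smaller difference was -49.5 kb, which argues against the replicate set. Loss of cohesin-held contacts of loop length may account for the pattern, as a hypothesis, since an effect of auxin without the degron was not tested. The depth behind the lists stays unknown.

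With 1 term for auxin over all 8 libraries, 673 promoters passed in long-range reads and 267 in all reads, and of the 35 splits of the libraries into 4 and 4 only 1, the real one, called as many in either test. The highest other counts were 0 and 3. The share of 0.0286, 1 split of 35, is the smallest possible. The other splits hold libraries with auxin on both sides, which widens the spread they are tested against and tends to keep their counts low. The rank of the real split therefore cannot exclude chance. For the screen 114 sgRNAs passed between days, and 1 of 35 splits, the real one, called as many, with 0 as the highest other. There the other splits hold libraries of both days on each side, with the same limit. The split by amanitin called 0 promoters in both tests.

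The control sgRNAs rose in ES cells from 2.08 to 2.72% of counts at day 0 to 4.38 to 5.52% at day 21. A candidate explanation is the loss of other sgRNAs when counts are scaled to totals, as Cdk19, Med12l and Med13l, genes with a paralog in the complex, had a median of -0.191 relative to the control sgRNAs. These 3 genes were picked after the result, and their partners Med12 (-2.41), Cdk8 (-0.67) and Med13 (-0.31) lay below the control. Relative counts cannot separate a loss of other sgRNAs from a rise of the control, so the 2 cannot be told apart.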
